A study of Mus musculus with 8 samples.

How the data were processed

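RNA sequencing was done on whole liver from male mice labelled Mdr2-/-, per the labels, 8 weeks old and given vehicle (PBS) or recombinant FGF21 (rFGF21) at 1.0 mg/kg for 4 h before the liver was taken. The series holds 4 samples per group. The labels call these separate samples and do not say outright that each came from its own animal, so p-values measure the spread between these samples. Per the labels' protocols, total RNA was extracted with Trizol and made into libraries with an Illumina TruSeq kit. That protocol text names retina as the tissue, while every tissue label says liver; the report gives marker genes of both tissues.

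The deposited table holds whole-number read counts per gene and library, per the file headers, for 30266 genes, together with the authors' FPKM values for 8 of its 10 count columns. Per the submitters' processing notes, Bowtie 0.12.2 and the mm8 build were used. The gene coordinates in the table do not belong to mm8: of 30266 gene identifiers, 30177 were in GENCODE mouse release 21 (build GRCm38). Of those 30177, 27322 (90.5%) had identical coordinates there. Coordinates are therefore given as the table prints them, as GRCm38. The counting tool, its strand setting and how reads shared between genes were assigned are not given in the sources used here. Counts of near-identical gene copies (Cyp4a12a and Cyp4a12b, the Cyp2c, Cyp2d, Mup, Saa and Pcdhg families, the alpha and beta globins) and of overlapping or antisense genes are uncertain for that reason.

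The table has 5 count columns per group against 4 samples per group. The 4 columns per group that also have an FPKM column were used, and 2 count columns were not used here. Why those 2 libraries lack FPKM values is not given in the sources used here, so whether they were set aside for a quality reason or for their values is not known. Column numbers differ from the sample numbers in the labels, so columns were assigned to groups and not to single samples; libraries are named by their group and the number in the column. Totals ran from 62756328 to 73313449 reads. No pair of libraries differed by as little as sampling noise; a chi-square statistic over genes, divided by its degrees of freedom, was at least 52.1 in every pair.

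The deposited counts were tested with edgeR 4.0.16 (R 4.3.3): genes with too few reads were removed with filterByExpr, libraries were scaled by TMM, and rFGF21 was compared with PBS by the quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided), without covariates. The 18315 tested genes were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. Every adjusted p of a gene in the text is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. Log2 fold changes are rFGF21 over PBS, and their standard errors (SE) follow from the F statistic. Levels are TMM-normalized CPM (read counts scaled by effective library size), as mean ± SD of 4 libraries. A group with 0 reads was set to a floor of 3 reads over the group, which covers counting error only. The design had been written for FPKM values or counts, and the count test became the main test because the table holds counts.

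A set of 39 gene lists was fixed before the data were examined. It covers bile acid synthesis, transport and regulators, FGF and ERK feedback, JNK components, immediate early genes, inflammation, interferon, acute phase, stress and p53 responses, fibrosis, hepatocyte metabolism and zonation, growth hormone, glucocorticoid and clock genes, proliferation, markers of other liver cell types and of other tissues, and RNA quality. The 35 lists with at least 5 tested members, apart from the sex genes, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, and again with an estimated correlation and with fry. For each list, members changed over all genes tested and members changed when adjusted over the list alone are given. GO and KEGG terms that the table attaches to genes were tested with one-sided Fisher's exact tests, separately for higher and lower genes, over 14679 tested genes with a term and terms of 10 to 500 members (3919 terms).

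The genes named were set by a rule fixed before the data were examined: the 15 largest increases and 15 largest decreases among changed genes whose groups did not overlap, leaving out predicted genes; up to 4 members with the smallest p in each list described; a fixed set of bile acid, FGF receptor, JNK and ERK genes; and up to 3 members of each term named. Markers of the tissue and sex labels were also fixed beforehand.

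On simulated counts with 50 genes at each of 4 fold sizes among 18315 genes, the edgeR step recovered 16% of genes changed 1.5-fold, 54% of those changed 2-fold, 74% at 4-fold and 90% at 8-fold, and 7 of its 124 calls (5.65%) were false. DESeq2 made 33 false calls among 169 (19.5%) on the same counts. These counts were drawn once, with edgeR's dispersions and 200 changed genes. The shares of false calls need not hold for the real data. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, robust fits, an adjusted p under 0.1, leaving out each library in turn, and limma on log2(FPKM + 1) with other pseudocounts, filters and scalings. FPKM for limma was computed from the counts and GENCODE exon lengths, since the authors' FPKM columns were not used here. Alternatives chosen after seeing the data were a bias-adjusted quasi-likelihood fit, leaving out mitochondrially encoded genes, leaving out PBS library 4 and rFGF21 library 5 together, and offsets for GC content and exon length.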

Results

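Liver RNA of male mice labelled Mdr2-/- was sequenced 4 h after PBS (4 libraries) or 1.0 mg/kg rFGF21 (4 libraries). Mdr2 is the older name of Abcb4, the phospholipid transporter of the bile canaliculus, and mice without it develop cholestatic liver injury. The study's title places the effect of FGF21 on this injury in FGFR4 and JNK signalling of the liver, and the comparison asks which liver transcripts differed after a short exposure to the hormone. The libraries held between 62756328 and 73313449 reads. Along the first principal component, which carried 25.7% of the variance, PBS libraries lay between -65.1 and -9.12 and rFGF21 libraries between 13.8 and 51.5.

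Marker genes were read before any comparison. Abcb4 (ENSMUSG00000042476, GRCm38 chromosome 5, 8893717 to 8959226) was read at 384 ± 36.3 CPM in PBS and 407 ± 28.7 CPM in rFGF21 libraries (SD, n = 4 each). Which part of the gene is disrupted in these mice is not given in the sources used here, so counts over the whole gene cannot check the genotype, and the libraries are called labelled Mdr2-/-. Albumin (Alb) stood between 42573 and 63437 CPM in the 8 libraries. The photoreceptor genes Crx and Rcvrn had 0 reads in every library, which allows up to 3 reads per library. Transcripts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were read in all 8 libraries, and Xist had at most 53 reads.

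Of 18315 genes tested, 516 changed after rFGF21, 210 higher and 306 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of over 2-fold were found in 51 higher and 84 lower genes. The smallest p belonged to Cacna1b, a pore subunit of neuronal calcium channels, which rose from 2.33 ± 0.52 to 15.3 ± 1.9 CPM, a log2 fold change of 2.72 ± 0.18 (SE). Depp1, a target gene of FOXO transcription factors, rose 12.5-fold from 11.6 ± 7.6 to 145 ± 49.7 CPM, and Cd14, a receptor for bacterial lipopolysaccharide, rose 3.00-fold. Other large increases were those of Pcdhgb8, Rgs16, Eps8l3, Duox2 and F13a1, with log2 fold changes between 1.48 and 2.54. Dio3, which inactivates thyroid hormone, and the aminopeptidase gene Lvrn had 0 reads in PBS and 93 and 58 reads over the rFGF21 libraries, at least 29.1-fold and 18.2-fold higher. The largest decreases were those of Adra1a, an adrenergic receptor (-2.73 ± 0.38), Lipg, endothelial lipase (-2.58 ± 0.32), G0s2, an inhibitor of triglyceride lipase (-2.53 ± 0.34), Noct, nocturnin (-2.40 ± 0.35), the lipid droplet gene Plin4 (-2.36 ± 0.46) and Cabyr (-2.34 ± 0.32). Angptl7, Cfap100, Lrit1, Lrit2, Pim3, Them5, Rpgrip1 and Mcm10 fell by 1.81 to 2.26 on the log2 scale. Several of these calls were lost with 7 libraries at fold changes of similar size. Leaving out rFGF21 library 1 ended those of Dio3 (edgeR adjusted p = 0.0588), Lvrn (0.0861), Rgs16 (0.0581), Pcdhgb8 (0.110), Eps8l3 (0.0786), Duox2 (0.104), F13a1 (0.0968), Plin4 (0.0988), Angptl7 (0.114), Cfap100 (0.0581), Lrit2 (0.0898), Pim3 (0.104) and Them5 (0.0726), and all of these but Dio3 also lost the call without at least 2 other libraries. Without rFGF21 library 1 the log2 fold change was 2.19 for Rgs16, 2.49 for Pcdhgb8, -2.31 for Cfap100 and -1.89 for Pim3. Plin4 kept its call in 13 of 27 alternatives, Lvrn in 8 of 17, Duox2 in 7 of 18, and Pcdhgb8 and Lrit2 in 9 of 18 each. Those of Cacna1b, Depp1, Cd14, Adra1a, Lipg, G0s2, Noct, Cabyr, Lrit1, Rpgrip1 and Mcm10 held whichever library was left out. The groups did not overlap in 510 of the 516 genes; over all genes tested this held for 12.3%, where chance gives 2.86%. The count differed with the library left out: it was 131 and 171 without rFGF21 libraries 1 and 5, 277 and 283 without rFGF21 libraries 2 and 3, and 207 and 251 without PBS libraries 1 and 5. With limma on TPM-scaled values, 362 genes were higher and 112 lower, and on FPKM values 238 were higher and 162 lower, against 179 and 238 with limma on median-of-ratios scaling and 210 and 306 with edgeR.

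**Figure D1:**
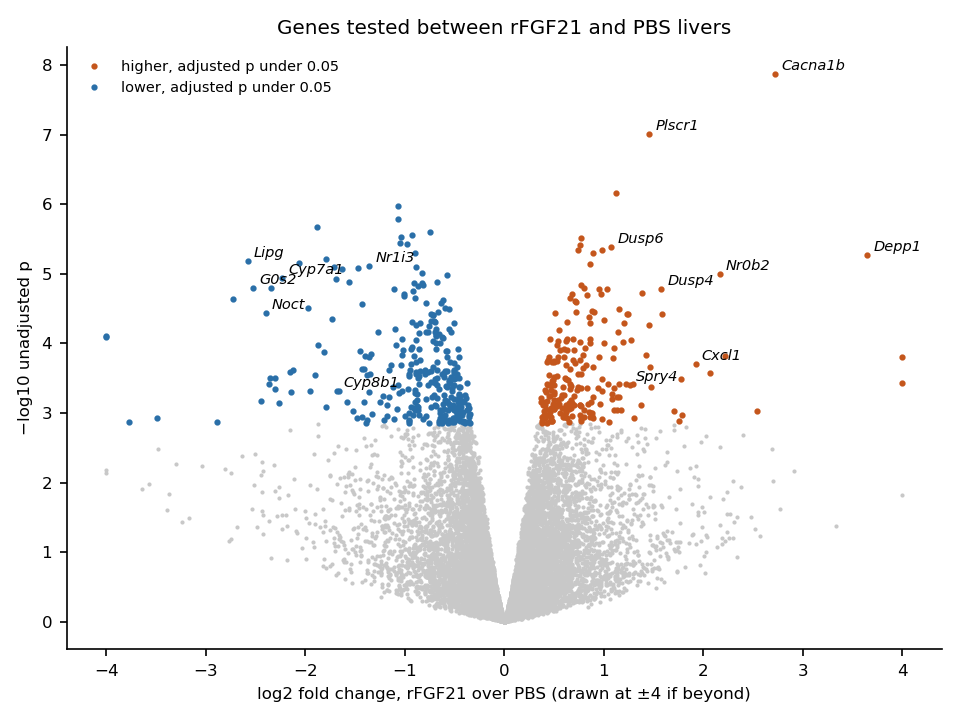
Each point is a gene, placed by its log2 fold change (rFGF21 over PBS, horizontal) and the -log10 of its unadjusted p from edgeR's quasi-likelihood test (vertical). Orange points are the 210 higher and blue points the 306 lower genes at an adjusted p under 0.05, and Cacna1b has the smallest p.

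Among genes of bile acid synthesis, Cyp7a1, the rate-limiting enzyme of the classic pathway (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633), fell 4.70-fold from 271 ± 110 to 57.7 ± 13.4 CPM (log2 fold change -2.23 ± 0.29 SE, n = 4 each, edgeR quasi-likelihood adjusted p = 0.00647, Benjamini-Hochberg). Cyp8b1, the sterol 12-alpha-hydroxylase that sets the share of cholic acid (ENSMUSG00000050445, chromosome 9, 121914356 to 121916305), fell 3.21-fold from 122 ± 63.7 to 38.0 ± 14.4 CPM (edgeR adjusted p = 0.0306). Cyp27a1 (-0.38 ± 0.10, edgeR adjusted p = 0.0775) and Cyp7b1 (-0.97 ± 0.29, edgeR adjusted p = 0.111), of the alternative pathway, did not pass. Of 18 list members, 2 fell and Ch25h, which makes 25-hydroxycholesterol, rose (1.78 ± 0.34); adjusted over the list alone, 10 were lower and 1 higher. The list as a whole was lower by camera (adjusted p = 1.5e-05), with a median log2 fold change of -0.34, and its adjusted p = 0.0565 with an estimated correlation. The Cyp7a1 call held whichever library was left out. That of Cyp8b1 was lost without PBS library 1 (edgeR adjusted p = 0.0539) or rFGF21 library 1 (0.0988), 3 (0.0806) or 5 (0.0764), and was kept in 19 of 28 alternatives. The call of Ch25h was lost without PBS library 1 or rFGF21 library 1, 2 or 5 (0.0581 to 0.0754).

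Among regulators of bile acid genes, Nr0b2, which encodes the repressor SHP (ENSMUSG00000037583, chromosome 4, 133553376 to 133556536), rose 4.49-fold from 5.57 ± 2.26 to 24.9 ± 6.1 CPM (edgeR adjusted p = 0.00606). Nr1h4, which encodes the bile acid receptor FXR, fell by 0.60 ± 0.11, and Nr1i3, the xenobiotic receptor CAR, fell by 1.36 ± 0.17. The 18 tested regulators and FGF receptors had 2 members higher and 2 lower (2 and 4 adjusted over the list alone) and were not called as a list (camera adjusted p = 0.593). Among 16 transporters of bile acids, Slc10a1, the main sinusoidal uptake carrier, fell by 0.80 ± 0.15 from 187 ± 35.1 to 107 ± 14.3 CPM, and Abcb1b rose by 0.80 ± 0.18; adjusted over the list alone, 3 were higher and 2 lower. Abcb1a (0.71 ± 0.17) and Atp8b1 (0.30 ± 0.08) did not pass. Abcb11, the bile salt export pump, stood at 334 ± 28.6 and 325 ± 74.1 CPM (edgeR adjusted p = 0.919), and its small difference changed sign under most limma settings. The transporter list was not called (camera adjusted p = 0.760). The calls of Nr0b2 and Nr1i3 held whichever library was left out. Nr1h4 lost its call without PBS library 1 or rFGF21 library 1, 2, 3 or 5 (edgeR adjusted p 0.0559 to 0.0653), Slc10a1 without PBS library 1 or 5 or rFGF21 library 1, 2 or 3 (0.0588 to 0.0648), and Abcb1b without any library but PBS library 4 (0.0582 to 0.123).

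**Figure D2:**
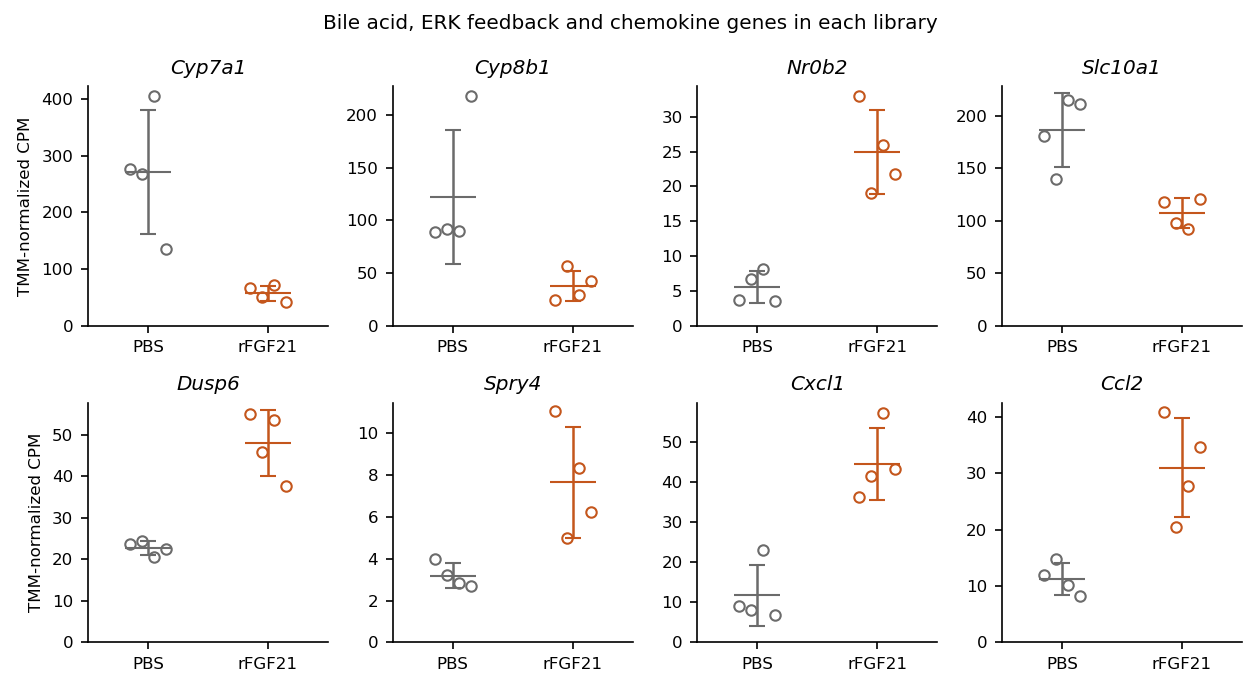
Circles are TMM-normalized CPM of single libraries on linear axes from 0, 4 PBS (grey) and 4 rFGF21 (orange); horizontal lines are means and bars are SD. In all 8 genes shown the groups do not overlap; Cyp7a1 fell from a mean of 271 to 57.7 CPM and Nr0b2 rose from 5.57 to 24.9 CPM.

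The list of FGF and ERK feedback also holds genes that are not inhibitors of the pathway, such as Etv5 and Lif. Of its 15 tested members, 6 rose and none fell. Dusp6, a phosphatase that inactivates ERK (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489), rose from 22.8 ± 1.7 to 48.0 ± 8.0 CPM (log2 fold change 1.07 ± 0.13, edgeR adjusted p = 0.00504). Dusp4, another MAP kinase phosphatase, rose by 1.58 ± 0.21, the ERK pathway inhibitor Spred1 by 0.76 ± 0.09, the ERK-induced transcription factor Etv5 by 0.96 ± 0.17, Spry4 by 1.26 ± 0.25 and the cytokine gene Lif by 1.70 ± 0.38. Adjusted over the list alone, 10 were higher. By camera the list was higher (adjusted p = 7.9e-12, median log2 fold change 0.76), with adjusted p = 0.0994 with an estimated correlation. Spry4 lost its call without any library except PBS library 1 or rFGF21 library 2 (edgeR adjusted p 0.0516 to 0.0800), Etv5 without PBS library 5 or rFGF21 library 1 or 5 (0.0512 to 0.0602), and Lif without PBS library 1, 4 or 5 or rFGF21 library 1, 3 or 5 (0.0727 to 0.0994).

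Among 28 immediate early genes, 4 rose and 1 fell (11 and 2 adjusted over the list alone). Klf6 rose by 0.97 ± 0.13, Ier3 by 1.10 ± 0.24 and Maff by 0.88 ± 0.19, while Dusp1, a phosphatase of JNK, p38 and ERK, fell by 1.41 ± 0.26. Fos was 0.96 ± 0.26 higher without passing (edgeR adjusted p = 0.0827), and Egr1 (0.30 ± 0.21) and Jun (0.03 ± 0.26) did not pass. The list was called higher by camera (adjusted p = 0.000522), with adjusted p = 0.104 with an estimated correlation. It lost that call in 8 limma settings, 0.541 at a mean FPKM of at least 5. Dusp1 lost its call without PBS library 1 or 5 or rFGF21 library 1 or 5 (edgeR adjusted p 0.0529 to 0.0719), Maff without PBS library 1, 2 or 5 or rFGF21 library 1, 2 or 5 (0.0522 to 0.113), and Ier3 without any library but PBS library 1 (0.0514 to 0.123).

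Components of JNK signalling had 3 of 21 members higher and none lower. Map3k1, a kinase upstream of JNK, rose by 0.91 ± 0.13 (33.3 ± 4.9 to 62.5 ± 9.6 CPM), and Dusp10 and Dusp16, phosphatases that inactivate JNK and p38, rose by 0.82 ± 0.15 and 0.57 ± 0.12. Map3k5 (0.39 ± 0.10, edgeR adjusted p = 0.0748) passed only when adjusted over the list alone, where 4 members were higher. The kinases themselves, Mapk8 (JNK1, 0.14 ± 0.11) and Mapk9 (JNK2, -0.12 ± 0.08), did not pass, and Mapk9 changed sign on TPM-scaled values. The list was called higher (camera adjusted p = 0.00837) although its median was 0.04, and its adjusted p = 0.249 with an estimated correlation. Transcript levels do not measure the phosphorylation of JNK or ERK, which was not analysed here. Dusp10 lost its call without PBS library 5 or rFGF21 library 1, 3 or 5 (edgeR adjusted p 0.0534 to 0.0686), and Dusp16 without PBS library 1 or 4 or any of the 4 rFGF21 libraries (0.0553 to 0.106).

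Among the FGF receptors named, Fgfr2 was the 1 that passed. It rose by 0.62 ± 0.11 (40.6 ± 3.9 to 62.6 ± 8.4 CPM, edgeR adjusted p = 0.0205). Fgfr4, the main FGF receptor of hepatocytes, stood at 59.0 ± 8.7 and 45.2 ± 4.5 CPM (-0.38 ± 0.12, edgeR adjusted p = 0.108) and passed only when adjusted over the list alone. Klb, the co-receptor of FGF21 (-0.33 ± 0.13), Fgfr1 (0.40 ± 0.21) and Fgf21 itself (-0.54 ± 0.27, 1.30 ± 0.28 and 0.89 ± 0.12 CPM) did not pass. Without PBS library 1 or rFGF21 library 1, the edgeR adjusted p of Fgfr2 was 0.0559 or 0.0756.

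Among 24 cytokine and inflammation genes, 3 rose and none fell. Cxcl1, a chemokine for neutrophils, rose 3.79-fold from 11.8 ± 7.6 to 44.5 ± 8.9 CPM, Ccl2, a chemokine for monocytes, rose 2.75-fold from 11.3 ± 2.8 to 30.9 ± 8.8 CPM, and the adhesion molecule Icam1 rose 1.60-fold. Adjusted over the list alone, 6 were higher. The list was higher by camera (adjusted p = 1.45e-06, median log2 fold change 0.59), with adjusted p = 0.0565 with an estimated correlation. Of 22 interferon genes 1 rose, Irf1 (0.70 ± 0.12), and of 23 acute phase genes 2 rose, the iron reductase gene Steap4 (0.94 ± 0.19) and the fibrinogen chain Fga (0.67 ± 0.15), with 6 acute phase members higher adjusted over the list alone. Both lists were called higher (camera adjusted p = 0.000653 and 0.000522), with adjusted p = 0.478 and 0.467 with an estimated correlation. Among p53 and apoptosis genes, 2 of 21 rose, the survival gene Bcl2l1 (0.77 ± 0.10) and Gadd45a (1.15 ± 0.24), with 4 higher adjusted over the list alone (camera adjusted p = 0.000424, and adjusted p = 0.276 with an estimated correlation). The endoplasmic reticulum stress list had Xbp1 as its 1 riser among 22 members (0.72 ± 0.11, camera adjusted p = 0.0230, and adjusted p = 0.185 with an estimated correlation), and that list lost its call without PBS library 4 (camera adjusted p = 0.0526) or rFGF21 library 2 (0.0614). The call of Cxcl1 was lost without PBS library 1 (edgeR adjusted p = 0.0646) or 5 (0.0501) or rFGF21 library 1 (0.0516), 3 (0.05004) or 5 (0.0534). Steap4 and Fga lost the call without any library but PBS library 4 (0.0504 to 0.0767 and 0.0615 to 0.0978), Gadd45a without any but rFGF21 library 2 (0.0570 to 0.104), and Irf1 without rFGF21 library 1 (0.0581) or 5 (0.0534).

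Few members of the fixed metabolic lists passed singly over all genes tested. The list of 25 cholesterol synthesis and SREBP2 genes was not called (camera adjusted p = 0.195), but was called lower without rFGF21 library 5 (5.56e-05). Of 25 genes of PPAR-alpha and fatty acid oxidation, Cpt2, the inner carnitine palmitoyltransferase, fell (-0.60 ± 0.09), and 8 were lower adjusted over the list alone. Slc25a20 (-0.56 ± 0.14), Acadm (-0.33 ± 0.10) and Hadha (-0.29 ± 0.09) passed only there. Among 20 lipogenic genes, Fads2 (-0.55 ± 0.12) and Dgat2 (-0.48 ± 0.11) fell, and 7 were lower adjusted over the list alone. Targets of growth hormone and STAT5 had 3 of 17 members lower, Cyp4a12a (-0.70 ± 0.11), Igfals (-0.70 ± 0.14) and the receptor Ghr (-0.60 ± 0.13), and 8 adjusted over the list alone. These lists were called lower by camera, with adjusted p = 2.12e-06 for fatty acid oxidation, 0.00112 for lipogenesis and 2.13e-05 for growth hormone. With an estimated correlation their adjusted p = 0.330, 0.301 and 0.0979. Dgat2 and Fads2 lost their calls in all but 1 of the 8 fits that left out a library, that without PBS library 4, and Ghr in all 8 (edgeR adjusted p 0.0537 to 0.122 for these genes). Over all 28 alternatives Dgat2 kept its call in 11, Fads2 in 10, Ghr in 8 and Igfals in 13. Igfals lost its call without PBS library 1, 4 or 5 or rFGF21 library 2, 3 or 5 (0.0530 to 0.0954).

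Pericentral hepatocyte markers had 3 of 15 members lower. Glul, glutamine synthetase, fell from 258 ± 25.8 to 157 ± 20.2 CPM, Slc1a2, a glutamate transporter, fell by 1.14 ± 0.21 and Cyp1a2 by 1.11 ± 0.25, and 6 were lower adjusted over the list alone. The camera call (adjusted p = 2.52e-06) had adjusted p = 0.104 with an estimated correlation. Periportal markers had 0 of 14 members changed (5 at an unadjusted p under 0.05, of which 4 were lower; DESeq2 called 1 higher and 1 lower, limma none), a median of -0.27, camera adjusted p = 0.0184, and adjusted p = 0.478 with an estimated correlation. Without PBS library 5 or rFGF21 library 5 the periportal call was lost (camera adjusted p = 0.0550 and 0.115), as it was after quantile normalization (0.400). Of 16 CAR and PXR targets, 2 fell, Cyp1a2 and Alas1, the entry enzyme of heme synthesis (669 ± 161 to 245 ± 85.6 CPM), and the list was not called (camera adjusted p = 0.136; 0.0482 without PBS library 1). Cyp2b10, the classic CAR target, was 1.39 ± 0.43 higher without passing (edgeR adjusted p = 0.114). Without rFGF21 library 1 the calls of Glul and Alas1 were lost (edgeR adjusted p = 0.0581 for each), and Slc1a2 lost its call without PBS library 1 or rFGF21 library 1, 2 or 5 (0.0515 to 0.0695). Cyp1a2 lost its call in 6 of the 8 fits that left out a library, keeping it without PBS library 2 or 4 (edgeR adjusted p 0.0823 to 0.125 in the others). Over all 28 alternatives it kept the call in 7, and in no limma setting.

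Markers of other cell types and of RNA quality were read in the same libraries. Of 18 cholangiocyte and ductular markers, 0 passed over all genes and 6 were higher adjusted over the list alone. Among the 6 were Krt19 (0.65 ± 0.20), Sox9 (0.62 ± 0.20) and Cd24a (0.58 ± 0.17). By edgeR 9 were higher at an unadjusted p under 0.05. DESeq2 called 5 higher, and limma called none of the 15 it tested. Of 25 fibrosis and stellate cell genes, Tgfb2 rose (0.85 ± 0.19), and 10 were higher adjusted over the list alone, with Col1a2 at 0.55 ± 0.16 and Timp1 at 0.55 ± 0.15. Neutrophil markers had 0 of 14 passing over all genes or adjusted over the list alone, with S100a9 at 0.89 ± 0.33. By edgeR 4 were higher at an unadjusted p under 0.05. DESeq2 called 0 markers, and limma called 0 of the 5 that passed its filter. Camera called the 3 lists higher (adjusted p = 0.000262, 1.07e-05 and 0.000769), with adjusted p = 0.406, 0.266 and 0.301 with an estimated correlation. The neutrophil list lost its call in 8 limma settings (camera adjusted p 0.0589 to 0.183). Limma on log2(FPKM + 1) tested only 5 of its 14 members, so that loss does not speak for the whole list. Lists of macrophage and Kupffer cell, endothelial, T and NK cell, and B and plasma cell markers had 0 changed members by edgeR and were not called (camera adjusted p = 0.228, 0.811, 0.383 and 0.852). At an unadjusted p under 0.05 they had 1, 1, 2 and 0 members. DESeq2 called 1 T and NK cell gene. Limma called 0 in each, but tested only 14, 15, 4 and 5 of the 16, 16, 16 and 11 members. The macrophage list was called lower without PBS library 2 (camera adjusted p = 0.0428) or rFGF21 library 3 (0.0282), and the endothelial list higher without PBS library 1 (0.0382). Mitochondrially encoded transcripts were lower as a list (median -0.49, camera adjusted p = 0.000424, and adjusted p = 0.467 with an estimated correlation) with 0 of 13 members passing (7 lower at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). They made up 7.96% of reads in PBS library 4 and 3.27% to 4.55% in the other 7 libraries, and without PBS library 4 the list call was lost (camera adjusted p = 0.0512). Ribosomal protein genes were not called (camera adjusted p = 0.841), with 0 of 32 changed by edgeR, DESeq2 or limma and 0 at an unadjusted p under 0.05; limma after quantile normalization called the list higher (0.00194). Tgfb2 lost its call without PBS library 1, 4 or 5 or rFGF21 library 1 or 5 (edgeR adjusted p 0.0751 to 0.127), and kept it in 10 of 27 alternatives.

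**Figure D3:**
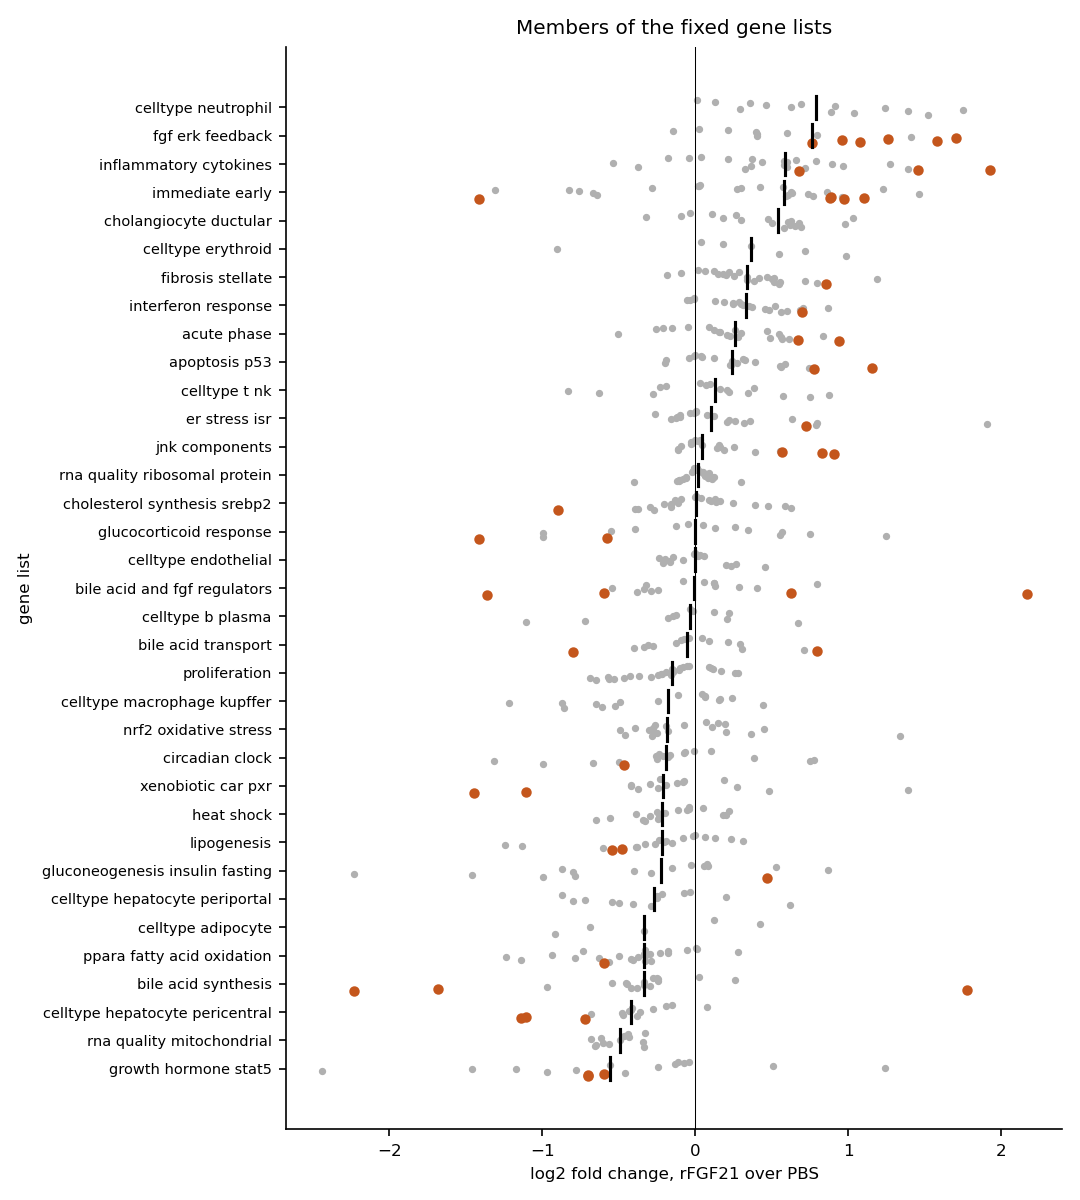
Each row is a fixed gene list, each point a tested member at its log2 fold change (rFGF21 over PBS, horizontal), and each black bar the list's median. Orange points passed edgeR's test over all genes. The list of FGF and ERK feedback, which also holds Etv5 and Lif, has 6 such points, all higher, and a median of 0.76.

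Annotation terms attached to the genes gave 84 enriched term and direction pairs among 3919 terms (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05), 62 for higher and 22 for lower genes. Lower genes were enriched for lipid metabolic process (33 of 458 tested members, adjusted p = 1.45e-07, with Lipg and Nr1i3), fatty acid metabolic process (17 of 170, with Mgll, Them4 and Acsl1), peroxisome (10 of 80, with Acsl1, Nudt7 and Pxmp4), bile acid signaling pathway (5 of 13, with Cyp7a1, Nr1h4 and Slc10a1) and NAD biosynthetic process (4 of 12, with Nmrk1, Aspdh and Afmid). Acsl1, which activates long-chain fatty acids, fell from 475 ± 89.6 to 236 ± 19.5 CPM, and the monoglyceride lipase Mgll fell from 85.8 ± 8.3 to 46.4 ± 6.0 CPM. Higher genes were enriched for cytokine-cytokine receptor interaction (17 of 199, adjusted p = 9.85e-06, with Tnfrsf12a, Csf1 and Cxcl14), inactivation of MAPK activity (6 of 17, with Spred1, Dusp6 and Dusp4), inflammatory response (16 of 275, with Tlr2, Csf1 and Cd14) and cell-cell junction organization (6 of 23, with Cxadr, Marveld2 and Flna). Tnfrsf12a, the receptor of the cytokine TWEAK, rose from 27.0 ± 3.0 to 58.9 ± 6.4 CPM, and Cxadr, a junction protein, from 166 ± 19.9 to 296 ± 29.6 CPM. The number of terms differed with the library left out: 5 to 8 terms were enriched without PBS library 1 or rFGF21 library 1 or 5, and 16 without PBS library 5. It was 30, 45 and 48 without rFGF21 library 3, PBS library 2 or rFGF21 library 2.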

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

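The count over splits of the libraries was planned; the tests on PBS library 4 and on GC content and gene length were chosen after the result was seen. Among 282 groups of 4 libraries examined, 22 held a library that stood apart from its group by Dixon's 95% criterion, where chance alone gives about 14.1.

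PBS library 4 stood apart in several measures: its mitochondrial share was 7.96% against 4.02% to 4.55% in the other PBS libraries, with mt-Nd2 at 5362 CPM, mt-Nd4 at 7104 CPM and mt-Atp6 at 6184 CPM. The same library held the highest PBS values of Cxcl1 (23.1 CPM, against 6.93 to 9.01), Xbp1 (273 CPM) and Dhcr7 (98.0 CPM), and the lowest of Nfil3 (7.75 CPM). PBS library 5 was high in Cyp8b1 (218 CPM, against 89.0 to 91.7), Cyp7b1 (48.9 CPM) and Tat (2995 CPM), and PBS library 2 in Adra1a (2.44 CPM).

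In the rFGF21 group, library 5 had 19092 genes with at least 10 reads against 18307 to 18415 in the others, and stood high in Camp (2.67 CPM) and Hsd17b7 (34.996 CPM). Library 2 had the lowest mitochondrial share (3.27%) and was high in Fgb (6609 CPM), Map3k5 (48.9 CPM) and Lvrn (0.325 CPM). Library 1 was low in Klf6 (53.2 CPM), and library 3 was low in Eps8l3 (0.986 CPM) and high in Angptl7 (0.260 CPM).

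The count of 516 changed genes was set against 3 technical readings. Of the 35 ways to split the 8 libraries into equal groups, 1 gave as many genes, the real split itself. The highest of the others gave 1 gene. That share is under 0.05 and is the smallest that 35 splits can give, so chance is unlikely but not excluded. The other splits mix both groups, so a group difference widens the spread within them and lowers their counts. Without PBS library 4, 373 of the 516 genes were still changed and their median log2 fold change was 0.966 of the value with it, which argues against that library as the whole cause. Fewer of them stayed changed without any other library. Among PBS libraries, 201, 304 and 223 did without library 1, 2 or 5. Among rFGF21 libraries, 126, 238, 261 and 168 did without library 1, 2, 3 or 5. Among these fits the losses were smallest without PBS library 2 and rFGF21 library 3. Each such fit has a smaller group and so less power, which by itself lowers the count. Reliance of the count on those libraries was therefore neither shown nor rejected. With per-library offsets for GC content and exon length, 457 of the 516 were still changed (515 had a GC value), which argues against such a bias. The treatment named by the labels stays the open biological reading, as a hypothesis, since collection order, cage and library batch are not given in the sources used here and cannot be separated from the groups.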

How the results depend on the processing

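All 516 changed genes kept their direction under every alternative that tested them. In 510 of them the groups did not overlap, so leaving out libraries could hardly reverse a direction and adds little support. The pair of libraries left out together and the offsets were chosen after the result was seen. The count moved with the filter, the tool and which library was left out. Without a filter, where 29484 genes were tested, it was 198 genes (85 higher, 113 lower, 10 terms). With DESeq2 it was 1527 (703, 824, 330 terms). DESeq2 made 19.5% false calls on simulated counts, a share that need not hold here. The count was 1061 (466, 595, 209 terms) at an adjusted p under 0.1, and 84 (40, 44, 1 term) with limma and no filter. The other limma fits tested fewer genes: 162 were lower on log2(FPKM + 1) and with robust fitting, 153 and 155 with pseudocounts of 0.1 and 0.01, 157 without a variance trend, 196 after quantile normalization, and 305 changed (127 lower) at a mean FPKM of at least 5. TPM scaling gave 362 higher and 112 lower and moved the median of all genes by 0.14, so changes there are relative to that shift; limma on median-of-ratios scaling gave 179 higher and 238 lower (42.9% higher, against 59.5% on FPKM and 40.7% with edgeR), so the split moved with the scaling. Leaving out PBS library 4 and rFGF21 library 5 together gave 223 (89, 134, 10 terms). Leaving out single libraries gave 131 to 486 changed, 51 to 198 higher, 80 to 288 lower, 5 to 84 terms and 17 to 23 lists. Of 70 named changed genes, 26 kept the call whichever library was left out, among them Cyp7a1, Nr0b2, Nr1i3, Dusp6, Dusp4, Spred1, Depp1, Cacna1b, Map3k1, Ccl2 and Icam1; limma with no filter ended those of Cyp7a1 (0.0519), Dusp4 (0.0505), Map3k1 (0.0694) and Ccl2 (0.0713), and leaving out both libraries that of Ccl2 (0.0561). The calls lost ranged from 13 without PBS library 4 to 43 without rFGF21 library 1.

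Of the 20 lists called by camera, 0 were called with an estimated correlation (7 at an unadjusted p under 0.05). Fry, which asks whether a list moves one way, called 8 (fry adjusted p 0.00299 to 0.0250). These were bile acid synthesis, cytokines, FGF and ERK feedback, growth hormone, endoplasmic reticulum stress, pericentral markers, immediate early genes and JNK components. The estimated correlation was under the preset 0.01 for bile acid synthesis (-0.0049) and endoplasmic reticulum stress (0.0028), and above it for the other called lists. In those 2 lists camera's unadjusted p still rose, from 2.57e-06 to 0.00225 and from 0.0125 to 0.0369. Correlation between members therefore cannot be why these 2 lists lost the call. Abcb11, uncalled throughout, was 0.0215 on log2(FPKM + 1) and with no filter, a mean FPKM of at least 5, no trend or robust fitting in limma, 0.0216 with either pseudocount, 0.11 on TPM and 0.078 after quantile normalization. With a library left out it ran from -0.200 to 0.0443 and Jun from -0.143 to 0.275. Mapk9 was 0.053 on TPM. Camera turned bile acid transport upward with no filter in limma (adjusted p = 0.935), after quantile normalization (0.981) and without PBS library 4 and rFGF21 library 5 (0.906), NRF2 targets upward in the last pair (0.644, 0.684), ribosomal protein genes downward without those libraries (0.732), endothelial markers downward on TPM (0.988) and B and plasma cell markers upward with GC and length offsets (0.987). Some uncalled lists turned with a library left out: camera adjusted p ran from 0.323 to 0.993 for bile acid regulators, 0.137 to 0.950 for B and plasma cells, 0.0382 to 0.948 for endothelium, 5.56e-05 to 0.993 for SREBP2 genes, 0.0289 to 0.950 for glucocorticoid genes, 0.0183 to 0.839 for NRF2 targets and 0.0980 to 0.999 for ribosomal protein genes. So 4 of these pass once a particular library is removed. Others also passed with a library left out, at their lowest 0.0282 for macrophages, 0.00351 for heat shock, 0.0113 for erythroid genes, 0.0482 for CAR and PXR targets and 0.000312 for gluconeogenesis, so these absences of a call are open. The cause was not tested.

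No paired analysis was possible because the columns could not be matched to the replicate numbers of the labels, and nothing in the sources used here shows that equal column numbers mark pairs. Depth was 62756328 to 73313449 reads per library, so genes such as Lvrn, with 58 reads over a group, rest on few reads.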

Other observations

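The tests of the hepatocyte share, of neutrophils and of the clock were chosen after the results were seen. Further gene groups fixed before the data were examined showed smaller or mixed changes. Among 18 clock genes, 5 were lower and 1 higher adjusted over the list alone; Per1 (-0.99 ± 0.25 SE, edgeR adjusted p = 0.0614), Nfil3 (-0.67 ± 0.18) and Hlf (-0.50 ± 0.15) did not pass over all genes. The list was called lower (camera adjusted p = 0.0184), with adjusted p = 0.249 with an estimated correlation, and lost the call without PBS library 4 (camera adjusted p = 0.0538). Glucocorticoid-responsive genes had 2 of 16 members lower, Dusp1 and Klf9 (-0.58 ± 0.11), while Mt2, a metallothionein gene, was 1.24 ± 0.31 higher without passing (edgeR adjusted p = 0.0628), and the list was not called (camera adjusted p = 0.513; lower without rFGF21 library 2, 0.0289). Of 16 genes of gluconeogenesis and fasting, Sesn1 rose (0.47 ± 0.11), and Ppargc1a (-0.79 ± 0.29) and Tat (edgeR adjusted p = 0.174) did not pass. That list was not called (camera adjusted p = 0.0614), but was called lower without PBS library 1, 2 or 4 or rFGF21 library 2, with no filter (0.0380) and in 7 limma settings (0.0101 to 0.0412). Klf9 lost its call without PBS library 1 or 5 or rFGF21 library 1, 3 or 5 (edgeR adjusted p 0.0529 to 0.0865) and Sesn1 without any library but rFGF21 library 3 (0.0629 to 0.132). Klf9 was kept in 20 of 28 alternatives and Sesn1 in 10 of 27.

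Proliferation genes had 0 of 28 members changed (2 lower at an unadjusted p under 0.05, 1 lower by DESeq2, 0 of 19 tested by limma). The list was called lower (median -0.16, camera adjusted p = 0.0338), with adjusted p = 0.742 with an estimated correlation. Its call was lost without PBS library 1, 2 or 4 or rFGF21 library 2 (camera adjusted p 0.0597 to 0.811). The replication factor Mcm10 is outside that list and fell from 53.4 ± 9.0 to 15.2 ± 6.8 CPM. Lists of heat shock genes, NRF2 targets, erythroid genes and adipocyte genes had 0 changed members by edgeR and were not called (camera adjusted p = 0.0540, 0.593, 0.0894 and 0.136). At an unadjusted p under 0.05 they had 6, 6, 4 and 3 members; DESeq2 called 1 NRF2 target and 4 erythroid genes, limma called 0, and 3 erythroid genes were higher and 1 lower adjusted over the list alone. Heat shock genes were called lower without PBS library 1 (camera adjusted p = 0.0113), PBS library 2 (0.00351) or rFGF21 library 3 (0.0282) and with no filter (0.0173). Erythroid genes were called higher without PBS library 5 (0.0292) or rFGF21 library 1 (0.0307) or 5 (0.0113). They were also called higher without PBS library 4 and rFGF21 library 5 together (0.0233), with GC and length offsets (0.0353) and with limma at a mean FPKM of at least 5 (0.0270). NRF2 targets were called lower without PBS library 5 (0.0183). Adipocyte genes were called lower with no filter (0.0133, and 0.0176 in limma) and on TPM values (0.00887). Pancreas, muscle and retina lists each had 2 tested members, none of them changed. The genes Lrit1, Lrit2 and Rpgrip1, known mainly from photoreceptors, fell from 5.47 ± 1.43, 1.38 ± 0.61 and 3.68 ± 0.57 CPM to 1.30 ± 0.32, 0.311 ± 0.142 and 0.997 ± 0.10 CPM, while Gnat1 and Rom1 of the retina list did not pass (edgeR adjusted p = 0.700 and 0.979).

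Lists of hepatocyte metabolism were called lower by camera and cytokine and ductular lists higher, calls that were all lost with an estimated correlation (adjusted p = 0.330 for fatty acid oxidation, 0.104 for pericentral, 0.0565 for cytokine and 0.406 for ductular genes). A lower share of hepatocytes in the rFGF21 livers is a candidate explanation. A score of 15 abundant plasma protein genes of hepatocytes differed by -0.08 ± 0.05 (SE) between the groups and the pericentral score by -0.49 ± 0.10. They moved apart by 0.4096 ± 0.1276 on the log2 scale (exact permutation p = 0.0571, smallest possible 0.0286). This gap is beyond 2 SE, but the exact test did not pass and the pericentral list was taken for comparison after its fall was seen. A lower share of hepatocytes is therefore left open. Other cell types did not separate beyond 2 SE (ductular minus macrophage score 0.740 ± 0.416, ductular minus endothelial 0.407 ± 0.344). A lower share of hepatocytes would raise the markers of all other cells alike. Ductular (0.43 ± 0.18), fibrosis and stellate (0.37 ± 0.10), erythroid (0.24 ± 0.17) and neutrophil scores were higher by more than their SE. Endothelial (0.02 ± 0.23) and T and NK (0.08 ± 0.22) scores did not rise beyond their SE. Neither did B and plasma (-0.05 ± 0.32) or macrophage (-0.31 ± 0.26) scores. With these SEs a small rise is not excluded, so the scores do not decide the question. More neutrophils as the source of the cytokine rise were also weighed. The neutrophil score was 0.8631 ± 0.3266 higher (exact permutation p = 0.0571), with no marker passing singly. Within groups, however, Cxcl1 and Ccl2 did not follow the score (correlations -0.459 and -0.427), which is against this source, on 8 libraries. It stays open because the score itself lay above PBS by more than its SE, and whole-liver RNA does not say which cells made Cxcl1 or Ccl2. A response of hepatocytes to rFGF21 remains a hypothesis.

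Cyp7a1, Cyp8b1, Nr0b2, Noct and Pim3, which have daily rhythms in liver, all changed, and a difference in clock phase at collection may have contributed. A clock score (Arntl arm minus Dbp arm, 12 genes) was 0.61 ± 0.26 higher in rFGF21 libraries (exact permutation p = 0.0857). With the score as a covariate, 0 of the 5 genes had an edgeR adjusted p under 0.05 and 1 of the 516 genes was still changed (1438 genes at an unadjusted p under 0.05), on 5 residual degrees of freedom in place of 6 and with wider errors. The 5 fold changes stayed beyond 2 SE: Cyp7a1 went from -2.23 ± 0.29 to -1.83 ± 0.33, Cyp8b1 from -1.68 ± 0.34 to -2.03 ± 0.52, Nr0b2 from 2.17 ± 0.28 to 2.32 ± 0.37, Noct from -2.40 ± 0.35 to -2.22 ± 0.50 and Pim3 from -1.95 ± 0.40 to -2.17 ± 0.57. Clock phase and treatment cannot be told apart for these genes, since the covariate ended the calls without removing the fold changes, the libraries are few, and the time of collection and feeding are not given in the sources used here. A difference in the score between the groups is itself not established.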
